A study of Mus musculus with 6 samples.

How the data were processed

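Kidney total RNA of C57BL/6 mice was extracted with Trizol and made into libraries with an Illumina TruSeq RNA kit from 1 microgram of RNA, per the labels' protocols. The 6 libraries, 3 labelled healthy and 3 labelled acute renal failure, were grouped by the diagnosis in the labels and are named by group and replicate number.

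The authors deposited counts per gene row for each library and 1 table of the whole series. Per the file headers, fragments were counted with featureCounts 2.0.1 over exons summed by gene name, keeping pairs with both ends aligned, leaving out chimeric pairs and ignoring strand; the annotation's build is not named there. The submitters' processing notes name Bowtie 0.12.2 and the build mm9, and the series' design text names BWA and TopHat with Cufflinks, so the notes and the headers differ. The aligner behind these counts is not given in the sources used here. The series table held the same counts for 53509 rows, without 37 mitochondrial rows that had 0 counts in every library.

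The deposited series table also holds a value per row and library named FPKM by the authors, treated here as a score because it is not an FPKM. In each library it was the FPKM computed from the count, the row length and the total, multiplied by a constant inversely proportional to the library total, so each value had been divided by depth 2 times. These deposited scores were used only in 1 alternative test.

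The start and end of 1394 of 49972 gene symbols (2.79%) were the same in the deposited rows and in the GENCODE M21 annotation of GRCm38. Counts nevertheless followed GRCm38 exons, as the report shows, so the rows appear to have been counted with intervals of another assembly than the reads lie on. Which assembly the intervals come from was not tested. Each row's intervals were intersected with GRCm38 exons with bedtools 2.31.1 in Python 3.11.15 with pandas 2.3.3. The exons were those of GENCODE M21 basic transcripts of protein-coding and long non-coding genes without read-through transcripts. A row was given to a gene when at least 0.9 of its overlapped exon bases, and at least 25 bases, belonged to that gene, and rows of the same gene were added. This gave 12401 rows, 9519 genes and 63.0% of the counts; 7759 of the genes had no row of their own symbol. A gene read this way is counted over part of its exons, so levels of different genes are not comparable, while the same bases are compared between libraries. Reads of an overlapping gene on the other strand or of a near-identical copy can be included. Naming genes by position was decided after the data were examined.

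The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, glmQLFit and glmQLFTest) with TMM normalization, filterByExpr, library totals over all rows and group as the only term. It was two-sided, with Benjamini-Hochberg adjusted p under 0.05 and no fold threshold. It was run on the deposited rows, as fixed before the data were examined, and on the genes read by position. Log2 fold changes are acute renal failure minus healthy as labelled, and CPM is relative to the library's total count; means are given with SD over n = 3 libraries. The SE of a log2 fold change is its size divided by the square root of the test's F statistic. The median log2 fold change of all genes read by position was 0.01 with TMM and 0.00 with DESeq2 size factors. With scaling by total count it was 0.19, so all changes are relative to that shift.

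The 33 gene lists were fixed before the data were examined and read by position. They were tested with camera (limma 3.58.1) at its preset correlation of 0.01 where at least 3 members passed the filter, adjusted over the lists other than markers of other tissues, blood, sex and handling, which are described only. No call of a list held when the correlation was estimated from the data, where the adjusted p was 0.180 or higher. In that setting p also rose for lists with an estimated correlation below the preset. The unadjusted camera p of endoplasmic reticulum stress (correlation -0.18) was 0.0340 at the preset and 0.0989 when estimated. That of cytokine and NF-kB response (correlation -0.04) was 0.0296 and 0.0918. A call lost in that setting therefore cannot be put down to correlation between genes alone. The fry test, which asks whether a list's genes move on balance 1 way, was run beside camera. It passed every list that camera called, with an adjusted p of 0.000536 for tubular injury and 0.0164 for proximal tubule. It also passed lists that camera did not: endoplasmic reticulum stress, cytokine and NF-kB response, cilium and nephronophthisis, oxidative stress, and macrophage and dendritic cell. Unlike camera, fry does not set a list against the other genes. With 2624 of 5246 genes called, a pass of fry does not mark a list as more changed than the rest.

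Genes whose group changes are given in the text follow a rule fixed before the data were examined, apart from Slc22a13, Dcn, Cp, Krt5 and the abundant genes. It takes the 10 largest rises and falls among called genes with non-overlapping groups and at least 5 CPM in the higher group, and up to 4 called members of each list with the smallest adjusted p. Where a list has no called member it takes the 2 with the highest mean, and 9 fixed genes are added. Some genes taken by this rule are not reported here, and they stay in the counts and list tests. Folds against a group with 0 counts use a floor of 3 counts over the group, and ratios with 1 to 3 counts in a group have exact 95% intervals; both cover counting error only.

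Depth ranged from 2873370 to 6191479 counts per library. Libraries of the same group correlated at 0.966 to 0.979 (Pearson, log2 CPM over rows) and those of different groups at 0.838 to 0.881. Within groups the chi-square per degree of freedom was 10.6 or more, so no library was a copy of another. The steps were tested on simulated data with the real depths and dispersions and with means over all 6 libraries. For genes read by position (5170 genes), 73.5% of 2-fold and 96.9% of 4-fold changes were called, and 0.161% of unchanged genes. For rows as deposited (10642 rows) these were 54.6%, 95.7% and 0.0958%. Few were changed in the simulation, in random directions: 98 genes read by position by 2-fold and 97 by 4-fold, and 97 and 93 rows. In the data 2624 of 5246 genes and 5045 of 10919 rows were called. The rates were not measured at such a share and cannot be carried over to the real test.

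Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter and a stricter filter on low counts, the replicate number as a block, each library left out, a 2-fold threshold and an adjusted p of 0.01. Others were added afterwards and are named where they are given. Figures were drawn with matplotlib 3.10.9.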

Results

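RNA libraries of C57BL/6 mouse kidney at postnatal day 21, 6 in number, were measured by paired-end RNA sequencing, with 3 libraries labelled healthy and 3 labelled acute renal failure. C57BL/6 is the standard inbred laboratory strain, and acute renal failure is a rapid loss of kidney function. The labels did not say how renal failure was brought about, nor whether the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries. The sample titles call the libraries labelled healthy control and those labelled acute renal failure treat, without naming a treatment. Total counts per library were 5710010, 2873370 and 3630813 in the libraries labelled healthy. In those labelled acute renal failure they were 5455886, 5525366 and 6191479. The groups are called healthy-labelled and ARF-labelled, because several marker genes moved against what the labels name.

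The gene name of most rows in the deposited tables did not belong to the reads counted in it. Umod and Kap, both abundant in kidney, had rows with 0 counts in all 6 libraries, while the row named Ltbp3 held the reads of Malat1. The row named Fubp3 held those of Ass1, a urea cycle enzyme of the proximal tubule. Rows that overlapped an exon of the mouse assembly GRCm38 made up 36.8% of all rows and held 99.0% of the counts (98.6% to 99.3% per library). In 20 copies of the row intervals shifted along the chromosomes, such rows held 44.9% to 63.9% of the counts, with a median of 51.2%. Of 73 ribosomal protein rows, 72 did not lie on their own GRCm38 exons, and those had a median of 0.374 CPM. The 11 ribosomal protein genes that could be read by position had a median of 501 CPM. Genes were therefore named by the GRCm38 exons under the counted intervals, which gave 9519 genes holding 63.0% of the counts. All gene names given from here on are names by position.

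**Figure D1:**
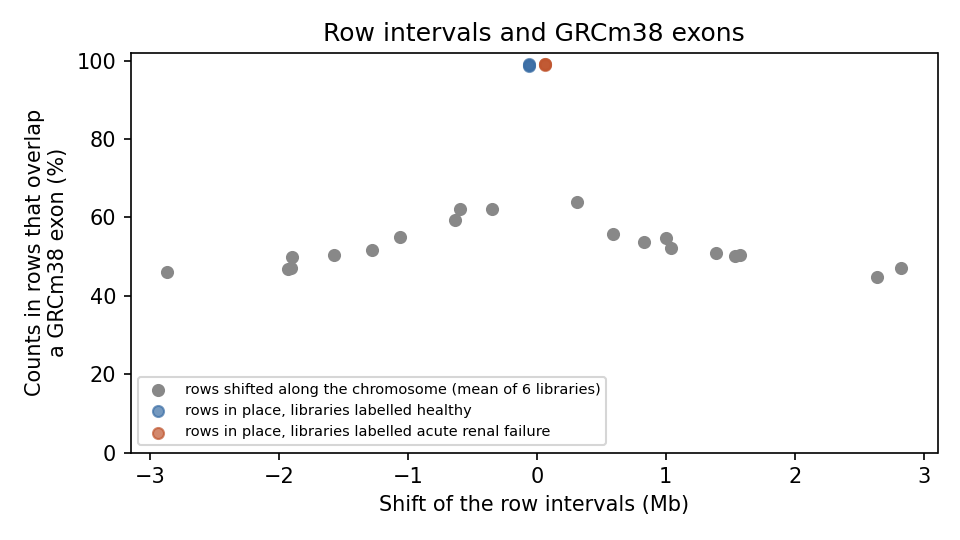
Percent of counts in rows that overlap a GRCm38 exon (y axis) against the shift of the row intervals along the chromosome in Mb (x axis). The 6 libraries with the rows in place, drawn side by side at a shift of 0, lie between 98.6% and 99.3%; the 20 shifted copies, each a mean over the libraries, lie between 44.9% and 63.9%.

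The comparison of the groups asks which transcripts differ between kidneys labelled acute renal failure and healthy at day 21. In the ARF-labelled libraries 9 of 10 tubular injury genes and 9 of 14 proximal tubule genes tested were lower, and 1 proximal tubule gene was higher. All 8 intercalated cell genes and all 4 principal cell genes of the collecting duct that were tested were higher. The lists held 32 tubular injury, 33 proximal tubule, 13 intercalated cell and 13 principal cell genes, and the rest could not be read by position. None of these 4 list calls held with an estimated correlation, where the adjusted p was 0.180, 0.514, 0.455 and 0.455 in the same order. In the values given, means are ± SD over n = 3 libraries, and a number followed by an SE is a log2 fold change, negative where the ARF-labelled libraries were lower. Krt8, a keratin of simple epithelia that rises in damaged tubules, stood at 5368 ± 772 CPM in the healthy-labelled and 854 ± 185 CPM in the ARF-labelled libraries (log2 fold change -2.82, SE 0.20, adjusted p = 2.63e-05). Tmem52b, a membrane protein gene, stood at 119 ± 38.5 CPM in the healthy-labelled and 2671 ± 694 CPM in the ARF-labelled libraries (log2 fold change 4.32, SE 0.30, adjusted p = 2.11e-05). Of 5246 genes tested by position, 1319 were higher and 1305 lower in the ARF-labelled libraries at an adjusted p under 0.05, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 599 and 710 differed by at least 2-fold. The groups did not overlap in 62.4% of the tested genes, against 10% expected by chance for 3 against 3 libraries. That 10% holds on average for a single gene. The share was not computed for other splits of the libraries, so it is no test against chance. Among the 10919 deposited rows tested under their own intervals, whatever their names, 2578 were higher and 2467 lower. The deposited values named FPKM were divided by the library total 2 times. A limma test on their logarithms, without TMM, called 519 rows higher and 2118 lower, so that 80.3% of the calls were lower, whereas 51.1% of the calls in the counts were higher.

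Among the 10 largest falls in the ARF-labelled libraries, Sprr2d and Sprr2f (chromosome 3, 92339140 to 92340873 and 92365187 to 92366442, GRCm38) encode small proline-rich proteins of epithelia under stress. Sprr2d had 228 counts in the healthy-labelled and 0 in the ARF-labelled libraries, at least 107-fold lower against a floor of 3 counts over the group. Sprr2f stood at 347 ± 43.4 CPM in the healthy-labelled and 1.26 ± 0.997 CPM in the ARF-labelled libraries (log2 fold change -8.29, SE 0.34, adjusted p = 4.31e-06). The Sprr2 genes are near-identical copies and Sprr2f was read through 34 exon bases, so both are uncertain. Fosl1, a transcription factor of the AP-1 family, stood at 87.8 ± 12.5 CPM in the healthy-labelled and 0.626 ± 0.310 CPM in the ARF-labelled libraries (log2 fold change -7.21, SE 0.25, adjusted p = 2.72e-06), and Akap12, a scaffold for protein kinase A, at 437 ± 18.2 CPM in the healthy-labelled and 6.17 ± 2.06 CPM in the ARF-labelled libraries (log2 fold change -6.32, SE 0.22, adjusted p = 2.72e-06). Vgf, the precursor of secreted neuropeptides (chromosome 5, 137026392 to 137033351), stood at 572 ± 386 CPM in the healthy-labelled and 1.10 ± 1.43 CPM in the ARF-labelled libraries (log2 fold change -9.11, SE 0.78, adjusted p = 5.05e-05). Il11, a cytokine of the interleukin-6 family, had 327 counts against 3, a ratio of 153-fold (95% interval 52.0 to 747) for counting error alone. The chemokine gene Cxcl3 had 246 counts against 4 (log2 fold change -6.51), and Tac1, which encodes substance P, had 62 against 1, a ratio of 87.2-fold (95% interval 15.1 to 3498). The long non-coding RNA Gm12505 had 276 counts against 0 (at least 129-fold lower), and Gp6, a platelet collagen receptor, 59 against 0 (at least 27.7-fold lower). Leaving out 1 library moved 6 of these log2 fold changes by more than 1.5-fold. That of Vgf was -8.39 without healthy-labelled replicate 1 and -11.05 without ARF-labelled replicate 3, that of Sprr2f was -9.09 without ARF-labelled replicate 1 and that of Cxcl3 was -7.71 without ARF-labelled replicate 2. The others have at most 3 counts in the ARF-labelled libraries, where the fitted value depends on the prior count. Il11 had -7.27 over all libraries, -8.08 without ARF-labelled replicate 1 and -6.66 without ARF-labelled replicate 3. Tac1 had -6.08 and -7.63 without ARF-labelled replicate 3, and Gm12505 -9.91 and -9.05 without healthy-labelled replicate 3.

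The largest rises were led by Adamts16, a secreted metalloprotease gene, with 2 counts in the healthy-labelled and 257 in the ARF-labelled libraries, a ratio of 91.4-fold (95% interval 25.05 to 759). Zkscan16, a zinc finger gene, had 3 counts against 308, a ratio of 73.0-fold (95% interval 24.8 to 356). Mill1, related to class I histocompatibility genes, had 3 against 88, a ratio of 20.9-fold (95% interval 6.91 to 103). Kcnj1, the potassium channel of the loop of Henle and the collecting duct (chromosome 9, 32372493 to 32399197, GRCm38), stood at 12.9 ± 4.96 CPM in the healthy-labelled and 192 ± 6.67 CPM in the ARF-labelled libraries (log2 fold change 3.75, SE 0.22, adjusted p = 1.03e-05). It was read through 67 exon bases in the row named Fli1. Fanca, a DNA repair gene of the Fanconi anaemia pathway, stood at 8.08 ± 1.51 CPM in the healthy-labelled and 128 ± 16.5 CPM in the ARF-labelled libraries (log2 fold change 3.79, SE 0.18, adjusted p = 6.11e-06). Gm13111, an antisense transcript, had a log2 fold change of 3.88 (SE 0.21), and since counting ignored strand its reads cannot be told from those of an overlapping gene. Atp10b (log2 fold change 3.93), Mgat4c (3.92) and Phkg1 (3.90) completed the 10 largest rises. All 20 of these genes passed the threshold in every fit that left out 1 library, but 4 log2 fold changes among the rises moved by more than 1.5-fold. That of Atp10b became 4.76 without healthy-labelled replicate 1. Those with at most 3 counts in the healthy-labelled libraries were 6.12 over all libraries, 5.31 without healthy-labelled replicate 1 and 9.24 without healthy-labelled replicate 2 for Adamts16, 4.05, 3.22 without healthy-labelled replicate 1 and 5.10 without healthy-labelled replicate 2 for Mill1, and 5.89 and 6.48 without healthy-labelled replicate 1 for Zkscan16.

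Of 10 tubular injury genes tested, 9 were lower in the ARF-labelled libraries and 0 higher, with the same counts when adjusted over the list alone. The list as a whole was lower (camera, adjusted p = 6.92e-08; adjusted p = 0.180 with an estimated correlation). Krt20, a keratin, had a log2 fold change of -3.87 (SE 0.21), and the stress cytokine Gdf15 one of -3.45 (SE 0.20). Clu, the secreted chaperone clusterin, stood at 6923 ± 2287 CPM in the healthy-labelled and 1352 ± 342 CPM in the ARF-labelled libraries (log2 fold change -2.54, SE 0.28, adjusted p = 0.000174). The remaining member Cp, which encodes ceruloplasmin, had a log2 fold change of -0.09 (adjusted p = 0.649). All 5 immediate early genes read, which answer within minutes to stress or handling, were lower too, among them Dusp1 (-3.02, SE 0.25), Junb (-2.47, SE 0.23), Ier2 (-2.49, SE 0.25) and Nr4a1 (-1.85, SE 0.43). Blood cell genes moved the same way: the neutrophil genes Mmp8 (-5.05, SE 0.57) and Csf3r (-3.70, SE 0.44) and the erythroid genes Hbb-bs (-3.37, SE 0.59) and Alas2 (-2.86, SE 0.41) were lower in the ARF-labelled libraries. Both neutrophil and both erythroid genes tested were called, too few for a test of either list.

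Among 14 proximal tubule genes, 9 were lower and 1 higher in the ARF-labelled libraries, and 10 lower and 1 higher when adjusted over the list alone (camera, adjusted p = 0.00100; adjusted p = 0.514 with an estimated correlation). Slc34a1, the sodium-phosphate cotransporter of the proximal brush border (chromosome 13, 55398187 to 55415592, GRCm38), stood at 2091 ± 469.9 CPM in the healthy-labelled and 384 ± 55.2 CPM in the ARF-labelled libraries (log2 fold change -2.62, SE 0.20, adjusted p = 3.31e-05). It was read through 160 of its 4026 exon bases, in the row named Gm47816. The sulphate transporter Slc13a1 had a log2 fold change of -2.04 (SE 0.19), the organic anion transporter Slc22a8 one of -2.38 (SE 0.23) and the amino acid exchanger subunit Slc7a7 one of -1.62 (SE 0.16). The member that was higher, Slc22a13, is another organic anion transporter (log2 fold change 1.91, SE 0.41, adjusted p = 0.00479); it is named here after its value was seen.

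Collecting duct genes went the other way. All 8 intercalated cell genes tested were higher in the ARF-labelled libraries (camera, adjusted p = 1.25e-06; adjusted p = 0.455 with an estimated correlation), and so were all 8 when adjusted over the list alone. The anion exchanger Slc4a1, also an erythrocyte gene, stood at 209.7 ± 78.9 CPM in the healthy-labelled and 1708 ± 252 CPM in the ARF-labelled libraries (log2 fold change 2.86, SE 0.27, adjusted p = 7.40e-05), while the erythroid genes above were lower. Rhbg, an ammonium transporter, had a log2 fold change of 2.16 (SE 0.17), the water channel Aqp6 one of 2.18 (SE 0.20) and the proton pump subunit Atp6v0d2 one of 1.65 (SE 0.14). All 4 principal cell genes tested were higher, over all genes and over the list alone (camera, adjusted p = 0.000330; adjusted p = 0.455 with an estimated correlation). They were the 3 subunits of the epithelial sodium channel, Scnn1a (1.27, SE 0.15), Scnn1b (1.59, SE 0.22) and Scnn1g (2.67, SE 0.15), and the water channel Aqp3 at 3224 ± 261 CPM in the healthy-labelled and 8297 ± 945 CPM in the ARF-labelled libraries (log2 fold change 1.19, SE 0.14, adjusted p = 0.000239). Upk3a, a urothelial gene, was higher as well (log2 fold change 1.86, SE 0.28). The other urothelial gene tested, Krt5, was not called (log2 fold change -0.57, edgeR adjusted p = 0.296), and the source of these reads was not tested.

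**Figure D2:**
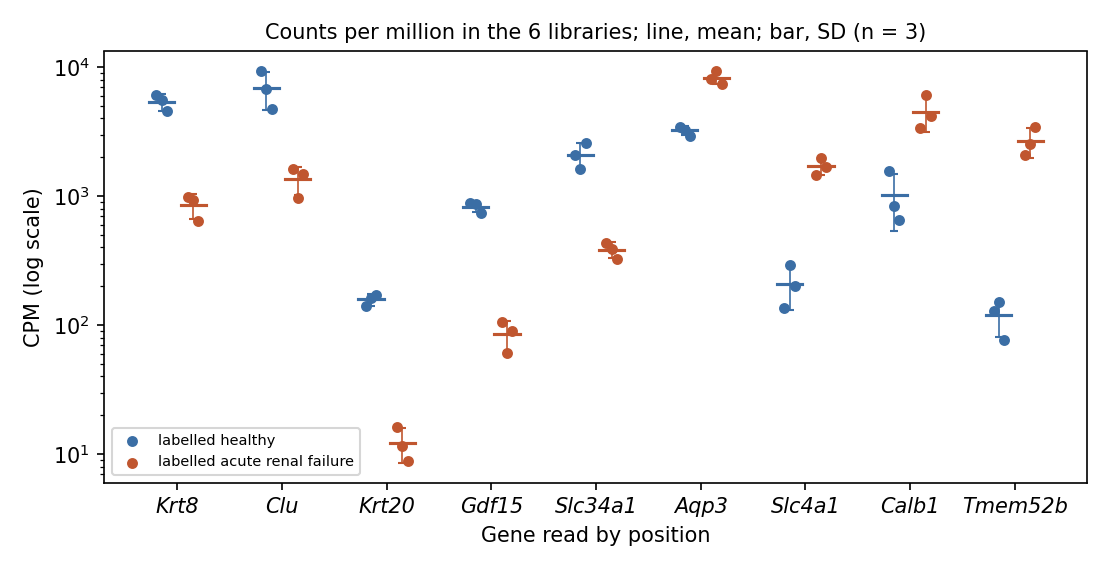
CPM on a log scale (y axis) of 9 genes read by position (x axis) in the 3 libraries of each label; points are libraries, lines are means and bars are SD (n = 3). For each gene the libraries of the 2 labels do not overlap, with Krt8, Clu, Krt20, Gdf15 and Slc34a1 lower and Aqp3, Slc4a1, Calb1 and Tmem52b higher in the ARF-labelled libraries.

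The other nephron segments were mixed. Of 4 loop of Henle genes, Kcnj1 and the transcription factor gene Pou3f3 (2.57, SE 0.71) were higher over all genes and over the list alone, and the other 2 were not called (camera, adjusted p = 0.0471; adjusted p = 0.514 with an estimated correlation). That list's adjusted p was 0.0849 without healthy-labelled replicate 1, 0.0729 without ARF-labelled replicate 1 and 0.0625 without ARF-labelled replicate 3. It was 0.835 for the 3 genes tested with at least 100 exon bases counted, which leaves out Kcnj1, a limit chosen after the data were seen. Pou3f3 lost its call without healthy-labelled replicate 1 (adjusted p = 0.0678), and its log2 fold change was 3.94 without healthy-labelled replicate 2. Of 3 distal convoluted and connecting tubule genes, the calcium-binding protein gene Calb1 was higher (1.98, SE 0.35), and the magnesium channel gene Trpm6 (-1.74, SE 0.31) and the calcium channel gene Trpv5 (-1.58, SE 0.40) were lower, also over the list alone. The list was not called (camera, adjusted p = 0.844), and the log2 fold change of Trpv5 was -0.97 without healthy-labelled replicate 1. Of 5 podocyte genes, Synpo, an actin-associated protein of foot processes, was lower (-2.37, SE 0.22) and Thsd7a higher (0.49, SE 0.17). Over the list alone Synpo was lower and no gene was higher (camera, adjusted p = 0.866); the list's median was 0.28 and its mean -0.20, so their signs differ. Thsd7a lost its call without healthy-labelled replicates 1 or 3 or ARF-labelled replicates 1 or 3 (adjusted p 0.0998 to 0.133).

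Immune, vascular and matrix genes that were called were mostly lower in the ARF-labelled libraries, but none of these lists passed camera in the main fit. Of them the macrophage and dendritic cell list passed fry, which does not set a list against the other genes. Passes of camera in alternative fits are given below and with the dependence on processing. Of 7 macrophage and dendritic cell genes 5 were lower, over all genes and over the list alone (camera, adjusted p = 0.0757; adjusted p = 0.754 with an estimated correlation; fry, adjusted p = 0.0347). They include the integrin Itgam (-2.41, SE 0.35), the protease Ctss (-1.29, SE 0.22) and the mannose receptor Mrc1 (-1.82, SE 0.39). Ccr2, a chemokine receptor, was lower (-1.36, SE 0.36) and lost its call without healthy-labelled replicate 3 (adjusted p = 0.0548). Of 16 matrix and myofibroblast genes 7 were lower and 1 higher, likewise over the list alone (camera, adjusted p = 0.0913; adjusted p = 0.919 with an estimated correlation; fry, adjusted p = 0.176). Among them were the collagen genes Col12a1 (-1.90, SE 0.33), Col5a1 (-1.68, SE 0.34) and Col5a2 (-2.15, SE 0.45, and -1.55 without healthy-labelled replicate 2). The member that was higher was Dcn, which encodes the proteoglycan decorin (0.88, SE 0.26, adjusted p = 0.0207). Of 6 endothelial genes 3 were lower, also over the list alone: Robo4 (-2.39, SE 0.29), Pecam1 (-1.29, SE 0.16) and Eng (-1.03, SE 0.25; camera, adjusted p = 0.222; adjusted p = 0.919 with an estimated correlation; fry, adjusted p = 0.121). Without healthy-labelled replicate 1 the adjusted p of these lists was 0.0169 for macrophages, 0.00178 for matrix and 0.0196 for endothelium. Without healthy-labelled replicate 2, the library with the highest Col1a1 and Lep, they were 0.157, 0.275 and 0.474 in the same order. Without ARF-labelled replicate 2 that of macrophages was 0.0475.

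Of 4 cytokine and NF-kB genes 3 were lower, over all genes and over the list alone: Nfkb1 (-1.10, SE 0.13), Relb (-1.61, SE 0.21) and the interleukin-1 receptor antagonist Il1rn (-3.39, SE 0.55; camera, adjusted p = 0.0757; fry, adjusted p = 0.00298). Of 7 interferon response genes, Psmb8 (-0.81, SE 0.21) and Oasl2 (-1.49, SE 0.45) were lower and Ifit2 higher (1.19, SE 0.38), also over the list alone (camera, adjusted p = 0.844). Oasl2 lost its call without healthy-labelled replicate 2 or ARF-labelled replicates 2 or 3 (adjusted p 0.0543 to 0.0749), and Ifit2 lost its call without healthy-labelled replicates 1 or 3 or ARF-labelled replicates 1, 2 or 3 (adjusted p 0.0551 to 0.0939). The lymphocyte list had 1 tested gene, the T cell kinase gene Lck, which was not called (log2 fold change -0.02, adjusted p = 0.966).

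Stress and growth arrest genes were lower where called, with 1 exception. Of 6 p53 response genes, Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 615 ± 63.3 CPM in the healthy-labelled and 60.6 ± 9.16 CPM in the ARF-labelled libraries (log2 fold change -3.52, SE 0.15, adjusted p = 4.31e-06). Btg2 (-1.73, SE 0.14) and Eda2r (-1.29, SE 0.34) were lower as well and Phlda3 was higher (0.48, SE 0.15), also over the list alone (camera, adjusted p = 0.0161; adjusted p = 0.497 with an estimated correlation). Phlda3 lost its call without healthy-labelled replicates 1 or 3 or ARF-labelled replicate 2 (adjusted p 0.0670 to 0.101). No cell cycle gene of 4 tested was called by edgeR, over all genes or over the list alone; at an unadjusted p under 0.05 the count was 0, and DESeq2 called 0. The ones with the highest mean were Mcm2 (0.32, adjusted p = 0.206) and Rrm2 (-0.45, adjusted p = 0.128; camera, adjusted p = 0.956). Rrm2 was called without healthy-labelled replicate 2 (log2 fold change -0.67, adjusted p = 0.0139). Of 3 endoplasmic reticulum stress genes, the asparagine synthetase gene Asns (-1.60, SE 0.10) and Edem1 (-0.45, SE 0.15) were lower, also over the list alone (camera, adjusted p = 0.0781; fry, adjusted p = 0.000896). Edem1 lost its call without healthy-labelled replicates 1 or 3 or ARF-labelled replicates 2 or 3 (adjusted p 0.0547 to 0.101). Of 4 oxidative stress genes, the cystine transporter Slc7a11 (-2.59, SE 0.50), the glutathione transferase Gsta2 (-1.55, SE 0.37) and Gclc, which encodes a subunit of an enzyme of glutathione synthesis (-0.42, SE 0.11), were lower, also over the list alone (camera, adjusted p = 0.288, and fry, adjusted p = 0.0233). The log2 fold change was -3.25 without ARF-labelled replicate 3 for Slc7a11 and -2.19 without ARF-labelled replicate 3 for Gsta2, and Gclc lost its call without ARF-labelled replicate 1 (adjusted p = 0.0585).

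Metabolic lists showed few shared shifts. Of 7 glycolysis genes, Hk2, the inducible hexokinase, stood at 119 ± 24.7 CPM in the healthy-labelled and 6.34 ± 1.52 CPM in the ARF-labelled libraries (log2 fold change -4.40, SE 0.23, adjusted p = 7.65e-06). Pfkp was lower (-0.68, SE 0.14) and Pfkl higher (1.20, SE 0.18), both subunits of phosphofructokinase; over the list alone 2 genes were higher and 2 lower (camera, adjusted p = 0.686). The median of this list was 0.20 and its mean -0.45, so the signs differ. All 4 sterol synthesis genes tested were lower, over all genes and over the list alone (camera, adjusted p = 0.0471; adjusted p = 0.541 with an estimated correlation). They include the regulator Srebf2 (-0.91, SE 0.12), Nsdhl (-0.71, SE 0.20) and Sc5d (-0.45, SE 0.13). That list's adjusted p was 0.0823 without healthy-labelled replicate 1, 0.0608 without healthy-labelled replicate 2 and 0.0729 without ARF-labelled replicate 1. With the same limit on exon bases it was 0.0529, and with all annotated transcripts, also chosen after the data were seen, 0.0581. Nsdhl lost its call without healthy-labelled replicate 3 or ARF-labelled replicates 1 or 2 (adjusted p 0.0567 to 0.0681), and Sc5d lost its call without healthy-labelled replicate 1 or ARF-labelled replicates 1 or 2 (adjusted p 0.0501 to 0.0806). Of 4 fatty acid oxidation genes, Acadl was lower (-0.68, SE 0.14) and the carnitine carrier Slc25a20 higher (0.53, SE 0.17), also over the list alone (camera, adjusted p = 0.866). Slc25a20 lost its call without healthy-labelled replicates 2 or 3 or ARF-labelled replicate 3 (adjusted p 0.0769 to 0.0929). Of 11 citrate cycle and oxidative phosphorylation genes, Idh3a was higher (0.36, SE 0.11), and none was called over the list alone (camera, adjusted p = 0.849). Idh3a lost its call without healthy-labelled replicates 2 or 3 or ARF-labelled replicate 2 (adjusted p 0.0661 to 0.107).

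Of 8 cilium and nephronophthisis genes, Bbs1 (0.96, SE 0.14) and Cep164 (0.68, SE 0.14) were higher, also over the list alone (camera, adjusted p = 0.222; fry, adjusted p = 0.00521). Of 3 kidney development genes, Wnt4 was higher (1.33, SE 0.24) and Hoxa11 lower (-1.21, SE 0.27), also over the list alone (camera, adjusted p = 0.866). Of 3 genes of the renin-angiotensin, klotho and vitamin D list, Ace, the angiotensin-converting enzyme gene, was lower (-0.95, SE 0.26), also over the list alone (camera, adjusted p = 0.866); the median of that list was 0.04 and its mean -0.22. Ace lost its call without ARF-labelled replicate 1 (adjusted p = 0.0538).

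**Figure D3:**
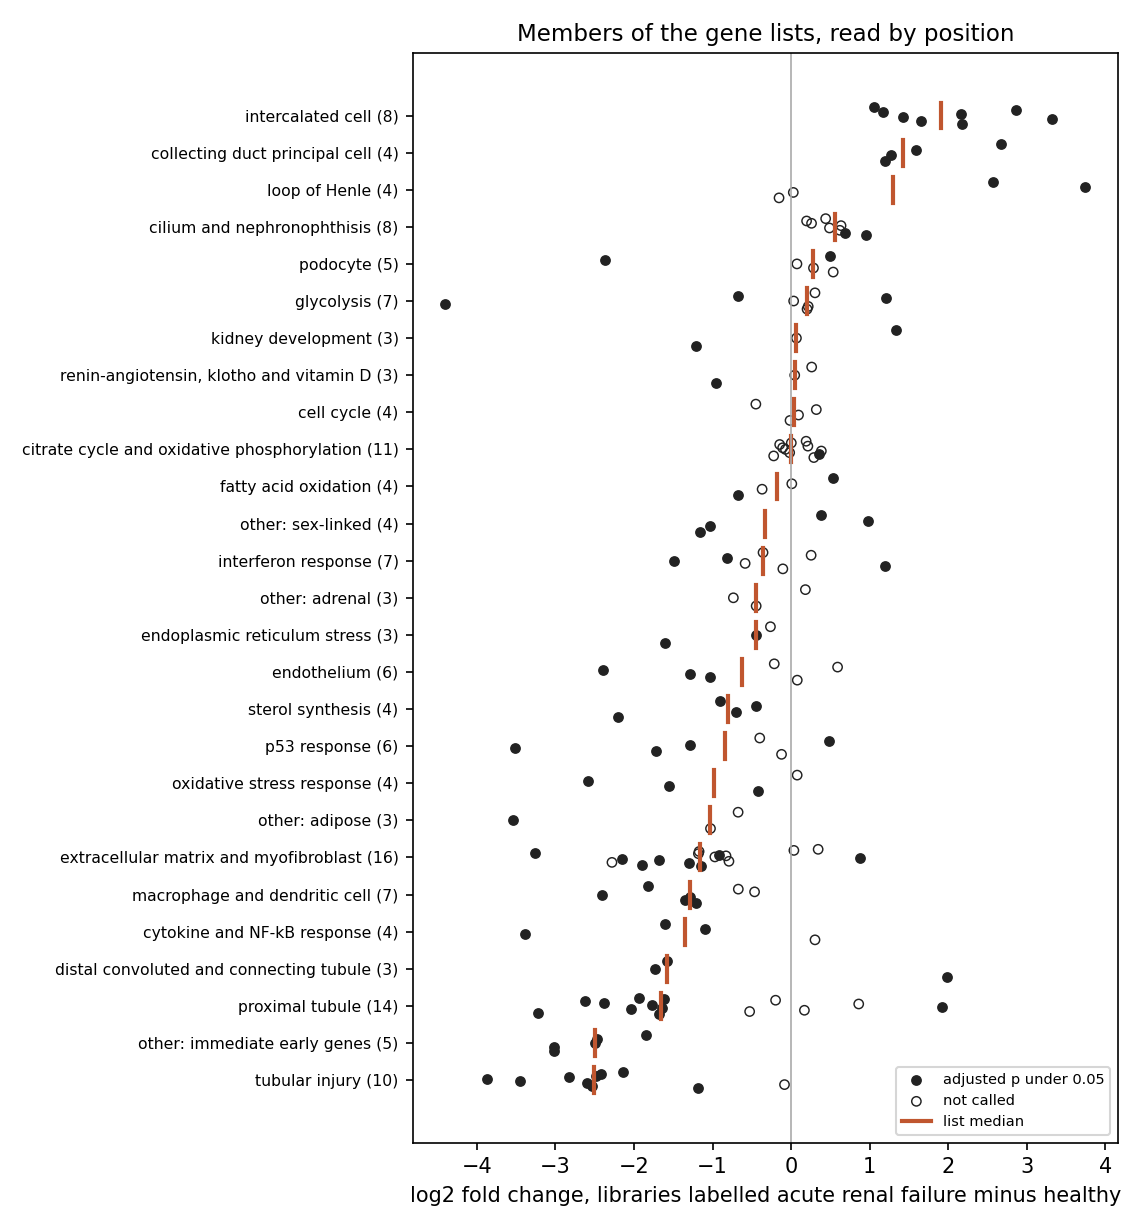
Log2 fold change of each tested list member, libraries labelled acute renal failure minus healthy (x axis), for the lists with at least 3 tested genes (y axis, number tested in parentheses). Filled points have an adjusted p under 0.05, open points do not, and the line is the list median, which runs from -2.51 for tubular injury to 1.91 for intercalated cells.

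Of 9 genes fixed for report in any case, Slc34a1 and Col1a1 could be read by position, and the others, among them Havcr1, Lcn2, Umod, Aqp2, Cd68 and Kl, were not analysed here. Col1a1, a fibrillar collagen gene, was not called (336 ± 445 CPM in the healthy-labelled and 76.4 ± 29.1 CPM in the ARF-labelled libraries, n = 3 each, edgeR adjusted p = 0.0674), and 1 library decided its value. Its log2 fold change was -2.28 over all libraries and -0.25 without healthy-labelled replicate 2. Without healthy-labelled replicate 1 it was called, at -2.82 with an adjusted p of 0.0157. Among the Y-linked genes, Ddx3y (-1.16, SE 0.11) and Eif2s3y (-1.04, SE 0.13) were lower and Kdm5d (0.98, SE 0.13) and Uty (0.38, SE 0.11) higher in the ARF-labelled libraries; Uty lost its call without healthy-labelled replicate 2 (adjusted p = 0.0683). Their lowest group mean was 96.9 CPM, for Kdm5d in the healthy-labelled libraries, and the labels give no sex. Of 3 adipose genes Lep was lower (-3.55, SE 0.94, and -1.85 without healthy-labelled replicate 2), and none of 3 adrenal genes was called by edgeR, by DESeq2 or at an unadjusted p under 0.05. The liver and skeletal muscle lists had no gene that passed the filter on low counts.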

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

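Each group holds 3 libraries, so no test for a library far from its group was made, and a single comparison leaves no effects to set against each other. The patterns weighed here were seen first; all tests below were chosen after that, and only the result of the thinning test was not known when it was planned.

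Gene names and counts disagree in the deposited tables: Umod and Kap have 0 counts, and ribosomal protein rows have a median of 0.374 CPM. A tissue other than kidney is argued against, since the 35 nephron segment genes read by position had a median percentile of 88.8 or higher among 9519 genes in every library. Genes are read over part of their exons, so the ranks are approximate; per counted exon base the median percentile was 84.5 or higher. A candidate explanation is that the rows hold gene intervals of another assembly than the reads lie on. Under it most counts need to lie in rows that happen to overlap GRCm38 exons, and 99.0% did, against 63.9% in the highest of 20 shifted copies.

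In the libraries labelled healthy 9 of 10 tubular injury genes were higher, a list call lost with an estimated correlation (adjusted p = 0.180), as were all 5 immediate early genes and the 2 neutrophil and 2 erythroid genes tested. Depth is argued against: after all libraries were thinned to 2873370 counts, 8 of the 9 injury genes still tested were lower in the ARF-labelled libraries. Exchanged group labels may account for the injury genes, but 9 of 14 proximal tubule genes were also higher in the healthy-labelled libraries and 1 was lower (median log2 fold change -1.66; adjusted p = 0.514 with an estimated correlation), so the tables leave this open. Handling before RNA extraction could raise immediate early genes, whose list had a median log2 fold change of -2.49, but their levels part the libraries exactly as the labels do, so handling and label cannot be told apart. A difference of the renal failure model itself stays open as well, untested.

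The counts of rows and genes called between the groups were set against the other splits of the 6 libraries into 3 and 3. The real split was 1 of 10 and called 5045 rows and 2624 genes by position, and the highest of the others called 0 rows and 0 genes. With 10 splits no share under 0.05 can be reached, so this comparison cannot decide on chance.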

How the results depend on the processing

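The alternatives on gene names by position, the adrenal-rich libraries and the deposited scores were chosen after the data were seen; the others were fixed before. No call of a named gene turned its direction: of 1419 values of 103 named genes over the alternatives, 1366 stayed on their side of the threshold, 49 lost a call, 4 gained one and 0 reversed a call. Among those not called, 11 values changed sign. Of the 97 genes called, 83 were called in every fit that left out 1 library. Slc22a13 and the abundant genes were named after their values were seen, and Dcn, Cp and Krt5 outside the naming rule. None of these was run through the alternatives unless the naming rule also took it. The number of rows higher in the ARF-labelled libraries was 2578, and 519 by limma on the deposited scores, 1208 at a 2-fold threshold and 1609 at an adjusted p of 0.01. The number lower was 2467, and 1375 at a 2-fold threshold. Leaving out 1 library gave 1961 to 2402 rows higher and 2015 to 2437 lower. Of the 2578 rows called higher in the counts, 147 had a negative change in the scores, and none of them was called lower there. That alternative changed the unit, the scaling and the test together, so the cause was not told apart. Genes by position numbered 1319 higher and 1305 lower, 599 and 710 at a 2-fold threshold, 851 higher at an adjusted p of 0.01, and 985 to 1183 higher and 1120 to 1313 lower without 1 library. Among rows lying on the gene they are named for, 370 genes were tested and 111 were higher and 111 lower, fewer because fewer genes were tested. Of these genes 98.6% had the sign of the main test. The same rows are part of the main counts of those genes, so this agreement was largely built in and is no test of the naming by position. Without the 2 libraries richest in adrenal transcripts, 1016 genes were higher and 1111 lower.

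Of 320 list values, 288 stayed on their side of the threshold. With an estimated correlation the adjusted p rose to 0.180 for tubular injury, 0.514 for proximal tubule, 0.455 for intercalated cell, 0.455 for collecting duct principal cell, 0.514 for loop of Henle, 0.497 for p53 response and 0.541 for sterol synthesis. With the deposited row names, which mostly name other genes, it was 0.550, 0.876, 0.866, 0.0650, 0.866, 0.866 and 0.970 in the same order, with the loop of Henle reversed in direction. With no filter on low counts it was 0.0295 for cytokine and NF-kB response, 0.0328 for matrix and 0.0295 for macrophages. With at least 100 exon bases it was 0.835 for the loop of Henle and 0.0529 for sterol synthesis, and with all annotated transcripts 0.0581 for sterol synthesis. Leaving out 1 library gave 0.0103 to 0.0849 for the loop of Henle, 0.00948 to 0.0823 for sterol synthesis, 0.00178 to 0.275 for matrix, 0.0169 to 0.157 for macrophages and 0.0196 to 0.474 for endothelium. The cause of these changes was not tested.

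The libraries gave no sign of pairing by replicate number. Same-numbered libraries of the 2 groups had correlations of their deviations of -0.07, -0.22 and -0.29, and no library correlated best with its own number. The highest correlation, 0.26, joined healthy-labelled replicate 2 and ARF-labelled replicate 3, the 2 libraries richest in adrenal transcripts. With 3 libraries per group, and such differences between them, these correlations cannot exclude a batch or litter shared by number. With the replicate block, 2238 rows were higher and 2210 lower, and 1135 and 1153 genes by position; the block brought matrix to 0.0487 and macrophages to 0.0487. The alternative pseudocount and the scaling of normalized values were not run, since the main test used counts. Healthy-labelled replicate 2 has the lowest depth, and genes under the filter on low counts were not tested.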

Other observations

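Among abundant genes, with at least 1000 CPM in the higher group and a change of at least 2-fold, 26 were lower and 17 higher in the ARF-labelled libraries. This group was chosen after the data were seen, and since genes are read over part of their exons, its limit follows level only roughly. The 26 include Gm42418, whose groups overlap and which reached the limit only through healthy-labelled replicate 3. Among the lower ones Ass1, which makes argininosuccinate, had a log2 fold change of -2.05 (SE 0.20), and Ugt3a2, a glycosyltransferase, one of -1.89 (SE 0.24). Others that were lower are Cdh1, which encodes E-cadherin (-1.16, SE 0.14), Itgav, an integrin chain (-1.48, SE 0.15), Sdc4, a cell-surface proteoglycan (-1.30, SE 0.12), and the non-muscle myosin gene Myh9 (-1.81, SE 0.14).

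The higher ones include Scd2, a fatty acid desaturase, at 173 ± 48.2 CPM in the healthy-labelled and 1404 ± 105 CPM in the ARF-labelled libraries (log2 fold change 2.85, SE 0.21, adjusted p = 2.63e-05). The vacuolar proton pump genes Atp6v1a (1.23, SE 0.18) and Atp6v1f (1.04, SE 0.13), the caveolin genes Cav1 (1.34, SE 0.22) and Cav2 (1.41, SE 0.19), the sorting receptor gene Sort1 (2.04, SE 0.21) and Rragd, a GTPase gene of nutrient sensing (1.25, SE 0.14), were also higher. Aqp3 and Calb1 have rows whose intervals lie on their own GRCm38 exons, so their values carry the same name in the deposited rows.

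Adrenal steroid genes varied between libraries of the same label. Cyp21a1 stood at 381, 1062 and 3.03 CPM in healthy-labelled replicates 1, 2 and 3, and at 79.4, 0.905 and 1769 CPM in ARF-labelled replicates 1, 2 and 3. Cyp11a1 was at 572 CPM in healthy-labelled replicate 2 and 619.6 CPM in ARF-labelled replicate 3, and had 0 counts in healthy-labelled replicate 3 and ARF-labelled replicate 2. Healthy-labelled replicate 2 also held Col1a1 at 848 CPM and Lep at 265 CPM, against at most 117 and 48.5 CPM in the other 5 libraries. Healthy-labelled replicate 3 held Gm42418, a gene overlapping a ribosomal RNA repeat, at 5707 CPM, against at most 398 CPM elsewhere.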
